A study of Mus musculus with 4 samples.

How the data were processed

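The series comprises RNA immunoprecipitation sequencing (RIP-seq) of hippocampus from C57BL/6 mice at postnatal day 40. Its 4 samples are 2 input libraries, made from lysate RNA without immunoprecipitation, and 2 libraries of RNA recovered with an antibody against YTHDF2. The tables analysed here have per-library values for the 2 input libraries alone. The 2 immunoprecipitated (IP) libraries were not analysed here, so the comparison of IP with input that the design names could not be made, and no enrichment or depletion is reported. Tissue was lysed with the buffer of a commercial RIP kit and RNA was extracted with Trizol, per the labels' protocols.

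The authors deposited raw read counts per gene and FPKM (fragments per kilobase of transcript, scaled to library size) values for 52636 mouse Ensembl genes. BWA 0.7.12, MACS2 2.1.0, HOMER and the GRCm38 build are named, per the submitters' processing notes. The read counter, its multi-mapping and strand settings and the gene annotation are not given in the sources used here. Each deposited FPKM value equals the count divided by the library's total count and by one length per gene. That length was whole and equal in both libraries for 100% of the 18734 genes with a count in both (tolerance 0.01 bases). In 90.9% of genes with a count it lay within 1 base of the mean length of the gene's GENCODE M21 transcripts. Among genes with more than 2 transcripts this share was 85.9%, against 0.518% for the longest transcript. FPKM therefore divides by an average over isoforms, and is high for a gene whose main transcript is longer than that average.

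The column numbers of the 2 input columns are not both replicate numbers of the sample titles, so the libraries are called by depth: the shallower (2563069 counts) and the deeper (3334451 counts). Gene names, types, GRCm38 positions and transcript sequences were taken from GENCODE M21, which is on the build the notes name. It held 52403 of the gene IDs. The other 233 carried 1585 and 2056 counts. No column of per-library values was left unused. A chi-square over the 12504 genes with at least 10 counts in both libraries was 11.6 per degree of freedom, so the 2 columns differ by more than counting error.

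Levels are CPM, counts scaled to a library total of 1e6 over all genes, given as mean ± SD over 2 libraries. The labels do not say whether the 2 inputs came from different animals, so the SD may be technical. A total of 3 counts, the limit that a count of 0 allows, corresponds to 1.17 CPM in the shallower and 0.900 CPM in the deeper library. Exact Poisson intervals (95%) of single-library levels, and exact binomial intervals (95%) of ratios between the libraries, cover counting error only. The ratio intervals leave out the 0.5 that is added to CPM in the ratios below. With few counts in a library they can therefore lie off-centre of the ratio. Ratios are log2 of deeper over shallower on the scale log2(CPM + 0.5), with trimmed mean of M values (TMM) factors of 1.05 and 0.951 from edgeR 4.0.16 over genes with a mean of at least 5 CPM. On this scale the median of genes at 20 CPM or more was 0.04. Without the factors it was -0.10. With 1 group there is no test and no p-value.

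The gene lists were fixed before the data were examined: 36 named lists and the Zfp family (names starting Zfp or Znf). The list symbols Ntn3, Norad, Rn7sl1 and Rn7sl2 matched no gene name used here. The median ratio of a list's members at 5 CPM or more was placed among 10000 random lists of nuclear protein-coding genes, each drawn from the 50 genes nearest to each member in mean level, or in transcript GC content. These percentiles describe these 2 libraries. Lists with under 5 such members were not placed. Sequence sharing was measured as the share of a gene's transcript 31-mers (1 in 16 sampled) that also occur in transcripts of another gene. On counts simulated for these 2 libraries with binomial splits over 6915 genes, the 2-fold limit found 200 of 200 genes changed 4-fold and 0 of 6700 unchanged genes, and a list shifted by 0.50 was placed at the 100th percentile. The simulation checks the computation only. It holds counting error alone, and the real libraries differ by more, so it does not give the rate of false calls in these data.

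The rule for named genes relied in part on test results between IP and input, which were not made here. Its first part, the YTHDF family and the reported YTHDF2 targets, was kept. In place of the others, and after the files had been opened, the text names the 4 members of a list with the highest mean CPM, the whole lists of m6A genes, mitochondrial mRNAs and nuclear noncoding RNAs, and the 12 genes with the highest and the 12 with the lowest ratio at 20 CPM or more, leaving out Gm and Rik names. Some genes that this rule names are not reported here. Rn7s1, Rn7s2, AY036118, Gm47299, Gm20431, Gm28437, Vamp2 and the sex-linked genes were chosen after their values were seen. The planned edgeR, DESeq2, camera, fry and limma comparisons of IP with input were not run. The alternatives tried for the values given here were other scaling factors (library totals, upper quartile, DESeq2 1.42.0 size factors), other minimum levels, other pseudocounts, other denominators, removal of the GC trend (running median over 21 bins) and leaving out each library. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3.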

Results

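Hippocampal lysate RNA of young mice was sequenced as the input of an RNA immunoprecipitation with an antibody against YTHDF2, a cytoplasmic protein that binds m6A-modified mRNA and promotes its decay. The series title states the purpose as finding the mRNA targets of YTHDF2 in the hippocampus. The labels give 2 groups of 2 libraries, input and YTHDF2 IP. The IP libraries were not analysed here, so no recovery by the antibody is described and the values are those of the 2 input libraries. With 1 group there is no test between groups and no p-value. The shallower library held 2563069 counts over 21693 detected genes, and the deeper held 3334451 counts over 21292. At least 10 counts were reached by 13534 and 13693 genes. Across the 12504 genes with at least 10 counts in both libraries, log2 CPM correlated at Pearson's r = 0.949 (Spearman's rho = 0.937); genes are not independent replicates. The biological coefficient of variation over 12218 genes was 0.259 (edgeR common dispersion).

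All 3 cytoplasmic YTHDF readers were detected in both input libraries. Ythdf2 (ENSMUSG00000040025, chromosome 4, 132184912 to 132212303, minus strand, GRCm38) had 137 counts in the shallower library and 117 in the deeper, a mean of 44.3 ± 12.98 CPM (SD, n = 2). Its level was 53.5 CPM (95% Poisson interval 44.9 to 63.2) in the shallower library and 35.1 CPM (29.0 to 42.1) in the deeper, so the libraries differed by more than counting error. Ythdf1 (chromosome 2, 180904377 to 180920949, minus strand) had 61.9 ± 1.98 CPM and Ythdf3 (chromosome 3, 16183212 to 16217037, plus strand) had 79.3 ± 21.1 CPM (SD, n = 2 each). The nominally higher level of Ythdf3 was within its own spread between libraries of that of Ythdf1. Ythdf3 went the other way from Ythdf2, with a log2 ratio of deeper over shallower of 0.69 (95% interval 0.42 to 0.97) against -0.46 (-0.83 to -0.10). By FPKM, which divides by transcript length, Ythdf1 was highest. It had 30.7 ± 0.983 FPKM, against 22.7 ± 6.04 for Ythdf3 and 21.8 ± 6.38 for Ythdf2, and the last pair differed by less than the spread between libraries.

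Among the other m6A readers, Prrc2a was the most abundant with 607 ± 170 CPM. Hnrnpa2b1 (77.1 ± 8.99 CPM), Hnrnpc (75.3 ± 6.02), Fmr1 (43.6 ± 1.53), Ythdc2 (40.3 ± 9.57) and Ythdc1 (33.7 ± 2.40) followed. The IGF2BP readers lay at or near the detection limit. Igf2bp3 had 8 and 11 counts in the shallower and deeper libraries, Igf2bp2 had 0 and 3, and Igf2bp1 had 1 and 0. Of the writers, the subunit genes Rbm15b (99.9 ± 16.6 CPM), Zc3h13 (64.4 ± 15.4), Rbm15 (63.0 ± 4.66) and Virma (47.9 ± 2.38) were highest by CPM. The catalytic subunit Mettl3 (9.60 ± 2.54 CPM) and its partner Mettl14 (16.2 ± 8.52 CPM) were lower. By FPKM, which divides by transcript length, Mettl3 (8.77 ± 2.32) lay beside Virma (8.43 ± 0.419) and Zc3h13 (10.5 ± 2.51). The length used for Mettl3 was 1095 bases, with 2159 for its longest transcript. Virma had 5677 of 6571 and Zc3h13 6151 of 6151, so part of the closeness can come from the divisor. Mettl3 had 20 and 38 counts. Rbm15b stayed highest (27.8 ± 4.60 FPKM). Wtap had 10.8 ± 1.77 CPM, Cbll1 18.6 ± 1.77 CPM and Mettl16 34.5 ± 6.87 CPM. The erasers Fto (166 ± 0.0195 CPM) and Alkbh5 (114 ± 1.65 CPM) differed little between the libraries. Mettl14, with 26 and 74 counts, was the 1 writer at least 2-fold apart. As groups, the 9 writers summed to 364.9 ± 1.80 CPM, the 2 erasers to 279.8 ± 1.63 CPM and the 12 readers to 1067 ± 161 CPM.

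**Figure D1:**
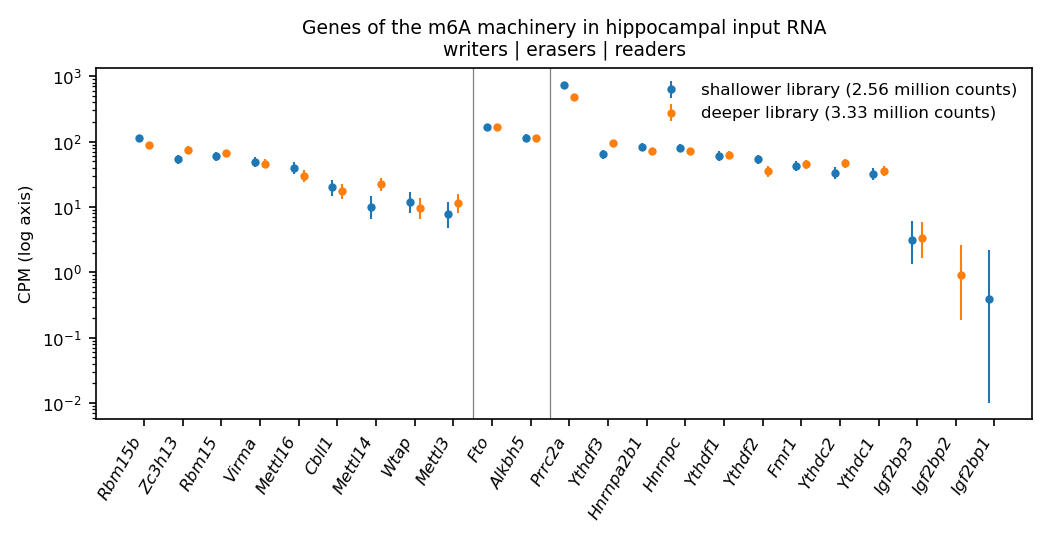
Level of each m6A writer, eraser and reader gene in the 2 input libraries, in CPM on a log axis; points are single libraries, bars are exact 95% Poisson intervals, and a library with 0 counts has no point. Ythdf2 lies at 53.5 and 35.1 CPM, and the Igf2bp genes lie lowest.

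The mRNAs of the general deadenylation and decay machinery were also present. Of 29 deadenylation and decay genes, 28 reached 5 CPM, with a sum of 1572 ± 2.28 CPM. By CPM the decapping helicase gene Ddx6 (278 ± 47.1 CPM) and the CCR4-NOT scaffold gene Cnot1 (159 ± 17.0 CPM) led the list. Pnrc1 (86.1 ± 4.22 CPM) and Pan3 (84.6 ± 11.5 CPM) came next. By FPKM Pnrc1 (83.4 ± 4.09) was above Ddx6 (53.5 ± 9.07) and Cnot1 (50.9 ± 5.44). Of 11 transcripts described as YTHDF2 targets in other cells, 9 reached 5 CPM in the input. Kalrn (650.0 ± 173 CPM), Hivep2 (595 ± 99.7), Son (426 ± 32.3), Crebbp (376 ± 21.3), Hspa12a (261 ± 31.6) and Islr2 (184 ± 12.99) were well measured. Wee1 (23.0 ± 12.2 CPM), Socs2 (13.6 ± 6.12) and Myc (5.99 ± 1.29) were low, and Tnfrsf1b (3.84 ± 1.19) and Nr1h3 (0.990 ± 0.296) lay under 5 CPM. The list's sum was 2540 ± 83.3 CPM. The log2 ratio of deeper over shallower was above 0 for 5 of the 9 and below 0 for 4.

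Synaptic transcripts were abundant in the input. Orders of genes within lists, here and below, are by CPM, which does not divide by transcript length. By FPKM Slc17a7 (494 ± 79.8) was above Bsn (157 ± 2.76), and Gria1 (317 ± 12.9) was above Grin2a (232 ± 22.6). Postsynaptic density genes summed to 19079 ± 1206 CPM over 38 members, all at 5 CPM or more, led by Camk2a (3925 ± 55.9 CPM), the alpha subunit of calcium/calmodulin-dependent kinase II, Shank1 (2122 ± 144), Camk2b (1078 ± 93.9) and Ppp1r9b (1065 ± 9.65). The 48 synaptic vesicle and release genes summed to 18757 ± 416 CPM, with Bsn (1836 ± 32.4), Cplx2 (1296 ± 0.380), the vesicular glutamate transporter gene Slc17a7 (1278 ± 206) and Syt1 (1175 ± 198) highest. Synaptic adhesion genes summed to 10047 ± 605 CPM over 47 members, led by Ptprs (919 ± 222), Clstn1 and Adgrl1. The NMDA receptor genes Grin2b (1845 ± 374 CPM) and Grin2a (1147 ± 112) and the AMPA receptor genes Gria1 (1087 ± 44.2) and Gria2 (589 ± 6.18) led the ionotropic glutamate receptor list, which summed to 7420 ± 267 CPM.

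Receptors, channels and signalling genes of other groups were measured as well. Metabotropic glutamate receptors summed to 868 ± 33.9 CPM, with Grm5 (505 ± 40.2) highest. GABA receptor genes summed to 2529 ± 194 CPM, with Gabbr1 (503 ± 86.6) highest. Voltage-gated potassium channels summed to 4348 ± 117 CPM. Sodium and calcium channels summed to 5366 ± 76.8 CPM, led by Cacna1e (849.5 ± 47.6) and Scn2a (701 ± 77.8). Memory and plasticity signalling genes summed to 14724 ± 1458 CPM, with the kinesin gene Kif5a (1451 ± 105) and the calmodulin gene Calm3 (1196 ± 137) among the highest. Genes of the immediate-early list, many of which neuronal activity induces, summed to 1318 ± 196 CPM. Of the 21 members at 5 CPM or more, 4 were at least 2-fold lower in the deeper library and 0 at least 2-fold higher. Homer1 (154 ± 7.28), Jund (152 ± 22.7), Arc (122 ± 37.1) and Egr3 (121 ± 14.998) led the list. Jund shares 49.0% of its 31-mers with other genes, so its count is uncertain. These are gene-level values and do not measure activity. Wnt signalling genes summed to 2509 ± 14.3 CPM (Gsk3b highest at 427 ± 17.1), axon guidance genes to 4635 ± 373 (Plxna4, 458 ± 21.9), chromatin modifiers to 7811 ± 467 (Chd3, 753 ± 33.1) and the 398 matched Zfp family genes to 8147 ± 42.7 (Zfp365, 413 ± 6.64).

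Markers of the main hippocampal cell types were detected in both libraries. Dentate granule cell markers summed to 945 ± 5.71 CPM, with Prox1 (219 ± 11.2) highest. CA1 and CA3 pyramidal cell markers summed to 1666 ± 124 CPM, with Nptx1 at 727 ± 94.0, and interneuron markers to 1683 ± 88.3 CPM, with Cnr1 at 349 ± 21.2 and Reln at 197 ± 12.2. Astrocyte markers summed to 6870 ± 798 CPM, most of it the glutamate transporter gene Slc1a2 (4588 ± 974). Oligodendrocyte markers summed to 4657 ± 6.97 CPM, led by the myelin gene Mbp (1546 ± 75.1), and precursor markers to 462 ± 19.0. Microglia markers were low at 285 ± 31.9 CPM, with Csf1r at 92.5 ± 7.75. Endothelial and pericyte markers (83.1 ± 12.7 CPM), blood markers (57.4 ± 4.38) and choroid plexus and ependymal markers (46.7 ± 12.2) were lowest. The choroid plexus gene Ttr had 7 counts in each library, and the 4 haemoglobin genes took 0.00525% ± 0.000349 of counts. The haemoglobin genes share at least 57.7% of their 31-mers with other genes, so their separate counts are uncertain.

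Housekeeping groups covered a wide range. Secreted and lysosomal protein genes summed to 8681 ± 1247 CPM, led by Cpe (1111 ± 249) and Apoe (869 ± 89.0), and proteasome genes to 805 ± 35.9. The nuclear-encoded respiratory chain summed to 2828 ± 242 CPM over 75 genes, with Atp5b at 528 ± 1.44. The 79 cytosolic ribosomal protein genes together reached 830 ± 5.97 CPM, below Camk2a alone, and 46 of them lay under 5 CPM. Rps15a (69.7 ± 13.01 CPM) and Rps3 (60.1 ± 17.2) were the highest. Processed pseudogenes that share at least 20% of their 31-mers with a ribosomal protein gene held 5634 ± 146 CPM, which was 6.79 times as many counts. The ribosomal protein genes share a median of 28.0% of their 31-mers with other genes, so how far their counts can be told from those of the copies is uncertain.

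Noncoding RNA took a large part of both libraries. The 7SL genes Rn7s1 and Rn7s2, the RNA of the signal recognition particle, held 7.15% ± 2.22 of counts (SD, n = 2). Genes annotated as rRNA together with AY036118 held 5.52% ± 0.449, the 7SK gene Rn7sk 1.77% ± 0.349, the RNase P RNA gene Rpph1 0.593% ± 0.203 and Malat1 0.814% ± 0.0782. Rn7s1 and Rn7s2 share 100% of their 31-mers with other genes, so their separate counts are not meaningful. Their sum leaves out Gm47299, which overlaps an end of Rn7s2 and held counts almost only in the shallower library. The sum may therefore be too low in that library. Gm47299 and Rn7s2 together had 77412 and 144910 counts (log2 ratio 0.67). Rn7sk, Rpph1 and Rmrp share 82.1%, 66.7% and 100% of their 31-mers with other genes, so their counts are uncertain too. Nuclear protein-coding genes held 75.9% (95% exact binomial interval 75.85 to 75.96) of the shallower and 71.5% (71.44 to 71.53) of the deeper library. The small structured RNA list, to which Rn7sk, Rpph1 and Rmrp belong, summed to 25831 ± 5686 CPM.

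The 2 input libraries differed most, as groups, in mitochondrial RNA. The mitochondrial genome gave 1.73% of counts (95% exact binomial interval 1.72 to 1.75) in the shallower library and 3.65% (3.63 to 3.67) in the deeper. All 13 mitochondrially encoded mRNAs were higher in the deeper library, 12 of them at least 2-fold, with a median log2 ratio of 1.46, above every one of 10000 random lists matched on level. Among them mt-Co1 had 18192 and 45546 counts (log2 ratio 1.09, 95% interval 1.06 to 1.11) and mt-Nd1 2110 and 6962 counts (1.49, 1.42 to 1.56), and mt-Nd6 had the smallest ratio, 0.83 (0.72 to 0.94). The mitochondrial rRNAs mt-Rnr1 and mt-Rnr2 were higher too, at 1.35 and 1.21, with a sum of 5274 ± 2782 CPM. The mRNA list summed to 21463 ± 10740 CPM. Of the 13 mRNAs, mt-Nd1 and mt-Atp8 share 0% of their 31-mers with other genes, and both had ratios near the median (1.49 and 1.46). Others share sequence with annotated pseudogenes, among which Gm28437 on chromosome 1 had 2249 and 8393 counts.

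Nuclear long noncoding RNAs went the other way, with 10 of 11 lower in the deeper library and a median log2 ratio of -0.29, at percentile 0.21 of level-matched lists. Snhg11 (-0.72, 95% interval -0.80 to -0.63), Miat (-0.50, -0.65 to -0.34) and Rian (-0.34, -0.47 to -0.21) were lower, Mirg had 101 and 19 counts, and Pantr1 was the exception at 0.53 (-0.24 to 1.38). Against lists matched on GC content the percentile was 3.16, inside the 95% range, and with the GC trend taken out the median was -0.34. The list summed to 10540 ± 1453 CPM, most of it Malat1 (-0.05, -0.08 to -0.03). Intervals of Neat1 (-0.35 to 0.27) and Peg13 (-0.25 to 0.02) included 0. Meg3, Rian and Mirg lie close together on the plus strand of chromosome 12, so they may not vary separately. Not all noncoding types at 20 CPM or more were lower. The median log2 ratio was 0.07 for 46 lincRNAs, beside 0.04 for nuclear protein-coding genes. It was -0.18 for 26 antisense genes and -0.27 for 18 processed transcripts.

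For the 33 lists that could be placed, chance puts 1.65 outside a 95% range if list members vary independently. It can put more there if they vary together. Outside the 95% range of level-matched random lists lay 5 lists. The other 3 were voltage-gated sodium and calcium channels (-0.10, percentile 1.0), axon guidance (-0.13, percentile 0.58, and 0.02 at a minimum of 50 CPM) and the Zfp family (0.05, percentile 99.0, and -0.09 without TMM factors, where the median of all genes was -0.10). All 3 lay inside the range once lists were matched on GC content. Synaptic vesicle genes lay above the GC-matched range (0.12, percentile 98.1) and inside the level-matched one. Without TMM factors their median was -0.02, where that of all genes was -0.10. Besides the mitochondrial mRNAs, this was the only list outside the GC-matched range. That makes 2 lists, where chance gives 1.65 if list members vary independently. Across 6308 protein-coding nuclear genes the ratio was lower at higher transcript GC content (Spearman's rho = -0.376). The median log2 ratio was 0.28 in the fifth of genes with the lowest GC (35.1% to 45.4%) and -0.14 in the fifth with the highest (56.1% to 71.6%). Medians of the other placed lists ran from -0.21 for microglia markers to 0.30 for small structured RNAs. Excitatory and inhibitory receptor lists were within their ranges, at 0.17 for ionotropic glutamate, 0.11 for metabotropic glutamate and 0.24 for GABA receptors, as were m6A writers (0.04) and readers (0.21). The median of the m6A readers was -0.12 with the GC trend taken out, and no direction is read from lists inside their ranges.

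**Figure D2:**
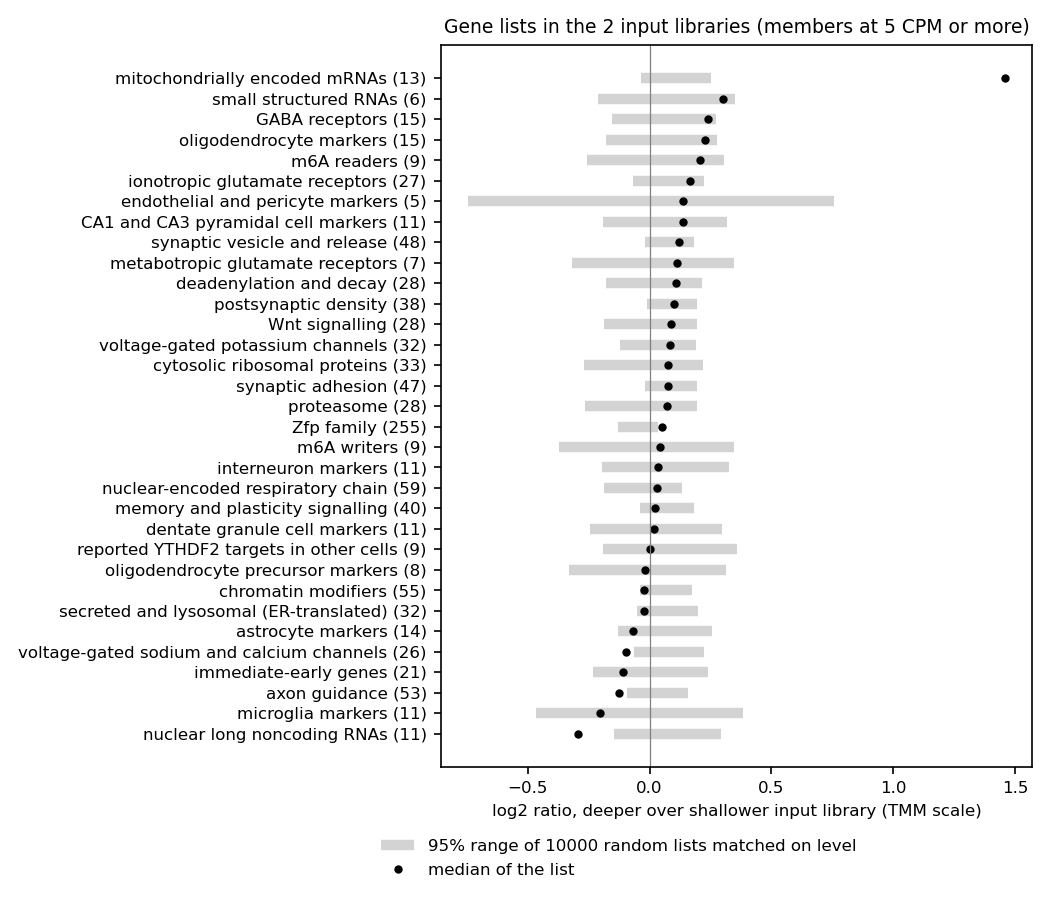
Median log2 ratio of deeper over shallower input library (horizontal axis, TMM scale) for 33 gene lists, with the number of members at 5 CPM or more in parentheses; grey bars are the 95% range of 10000 random lists matched on level. The mitochondrially encoded mRNAs lie apart at 1.46.

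Single genes mostly agreed between the libraries. Of 6915 genes with a mean of at least 20 CPM, 84.4% lay within 1.5-fold and 272 (3.93%) were at least 2-fold apart, 137 higher in the deeper library and 135 higher in the shallower. At a minimum of 5 CPM 1164 genes were at least 2-fold apart, and at 50 CPM 88. In 100 binomial splits of the same counts, which hold counting error alone, at most 1 gene was 2-fold apart. Some well-known neuronal and housekeeping genes were among the 47 that were at least 4-fold apart. Adcy1, a calcium-stimulated adenylyl cyclase, had 4753 counts in the shallower library and 634 in the deeper (log2 ratio -3.14, 95% interval -3.26 to -3.02). Snph, which encodes syntaphilin, had 1614 and 180 (-3.39, -3.63 to -3.18), and the cap-binding protein gene Eif4e had 163 and 10 (-4.06, -5.35 to -3.35). Rab35 had 148 and 7 counts, and Ackr1 had 107 and 0.

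In the other direction, Vapb had 5 and 453 counts (5.93, 95% interval 5.03 to 7.90). The potassium channel subunit gene Kcnab2 had 204 and 2019 counts (3.06, 2.86 to 3.29), and Lrrc4b, a synaptic adhesion gene, 52 and 814 (3.70, 3.33 to 4.17). Hnrnpa3 had 17 and 329 counts, with 28.1% of its 31-mers shared with other genes. Ube2v1 had 2 and 219 counts while Gm20431, which overlaps it, had 182 and 0; their sums were 184 and 219. Values of such genes in these input libraries are not reliable to within several fold, and a mean over the 2 libraries describes neither.

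**Figure D3:**
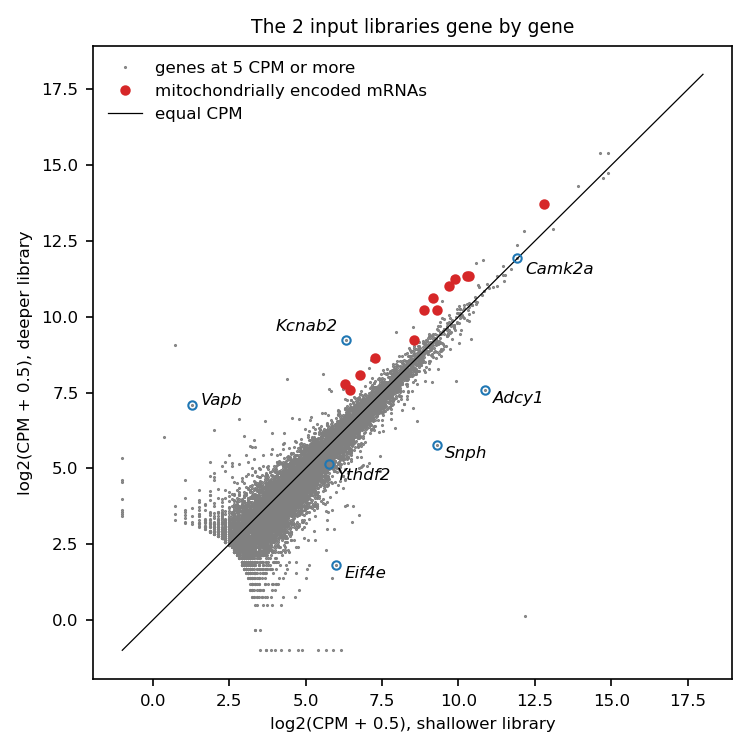
Level of each gene at 5 CPM or more in the shallower (horizontal) and deeper (vertical) input library, as log2(CPM + 0.5), with the line of equal CPM. The mitochondrially encoded mRNAs (red) lie above the line, and Vapb (5 and 453 counts) and Adcy1 (4753 and 634 counts) lie far from it.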

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

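All alternatives here were chosen after seeing the data. The planned ones (DESeq2, other factors and filters, a minimum fold, limma on FPKM, length offsets, replicate blocks, fry, camera with estimated correlation, leaving out libraries) concerned IP against input and were not run. No paired analysis was possible because IP values were not analysed here. The direction of the mitochondrial and nuclear noncoding RNA medians and of the GC trend held under every alternative run, except that taking the GC trend out brought its own correlation to -0.0049 by construction. Without TMM factors the mitochondrial mRNA median was 1.31 and the nuclear noncoding median -0.44, and with the GC trend taken out they were 1.12 and -0.34. The number of genes at least 2-fold apart was 1164 at a minimum of 5 CPM and 88 at 50 CPM. With 20 CPM as the minimum it ran from 233 to 315. The GC correlation was -0.288 at 5 CPM and -0.448 at 50 CPM. Without mitochondrial genes, rRNA, 7SL and 7SK in the totals Ythdf1 had 74.8 CPM, and with only nuclear protein-coding counts in the totals Ythdf1, Ythdf2 and Ythdf3 had 84.1, 59.8 and 108 CPM. Single libraries gave 60.5 and 63.3 CPM for Ythdf1, 35.1 and 53.5 for Ythdf2, 64.4 and 94.2 for Ythdf3, and 1.73% and 3.65% for the mitochondrial share. Of 210 medians of the other lists under the alternatives, 34 lay on the other side of 0, 17 of them without TMM factors, which moves all genes alike (their median from 0.04 to -0.10) and so says nothing of a single list. The largest of the 34 was that of the m6A readers, from 0.21 to -0.12 with the GC trend taken out. By size, 170 of the 210 moved by less than the spread of random lists. Of the lists outside their level-matched range, 2 changed sign. The Zfp family was at -0.092 without TMM factors, beside the median of all genes. Axon guidance was at 0.023 at a minimum of 50 CPM, where fewer members enter; the cause was not tested further. At 2563069 and 3334451 counts, a level of 5 CPM is fewer than 20 counts in either library.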

Other observations

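The tests of pseudogene counts and longest exons of ribosomal protein genes, and of the GC trend for mitochondrial mRNAs and for genes at least 4-fold apart, were fixed before their results were seen. All other tests in this part were chosen after. Transcripts of Y-linked genes were counted in both input libraries: Ddx3y had 89 and 183 counts, Uty 99 and 94, Kdm5d 75 and 71, and Eif2s3y 17 and 29, in the shallower and deeper library. Xist, expressed from the inactive X chromosome of females, had 0 and 2. Vamp2, a vesicle fusion protein gene, had 2456 and 791 counts, although the synaptic vesicle list as a whole differed little. Gm47299, an annotated miRNA that overlaps an end of the 7SL gene Rn7s2, had 11825 and 2 counts.

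The 79 ribosomal protein genes held few counts in both libraries, which is unusual for transcripts of such high abundance in most tissues. Processed pseudogenes with sequence of these genes held 6.79 times as many counts, which fits reads of spliced ribosomal protein mRNA being placed on intronless copies. The processing notes name BWA, which does not align across introns; if the counts rest on it, a read over an exon junction may place better on a processed pseudogene. Whether short exons add to the loss stays open: across the 79 genes FPKM and the longest exon correlated at Spearman's rho = 0.188, with a 95% bootstrap interval from -0.04 to 0.41. FPKM was not clearly lower in genes with more shared 31-mers either (rho = -0.123, -0.359 to 0.135), and no biological explanation was tested.

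Of genes apart between the 2 input libraries, 272 were at least 2-fold apart against at most 1 in any of 100 binomial splits, but such splits hold counting error alone and say nothing of what else separates 2 libraries. Sequence shared with other annotated genes does not account for most of the 47 genes at least 4-fold apart: 12 of them had over 20% of their 31-mers in another gene (25.5%, against 14.6% of other genes), and 15 had under 1%, among them Adcy1, Snph, Vapb and Lrrc4b. For pairs of overlapping genes a split between them may still be the source, as the sum of Ube2v1 and Gm20431 differed by a log2 ratio of only 0.02. The GC trend by itself was too small to make a 4-fold difference. Its median log2 ratio ran from 0.28 in the group of genes with the lowest GC content to -0.14 in the group with the highest. With it taken out 44 of the 47 stayed 4-fold apart, which a trend of this size could hardly have changed. Effects of GC content on single genes were not tested. A difference between the libraries in how reads were counted to isoforms, and a difference between the tissues, stay open and untested.

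The higher mitochondrial mRNAs of the deeper library were not accounted for by the GC trend, as their median of 1.46 lay at percentile 100 of GC-matched lists, and 1.12 remained with the trend taken out. More expression of the respiratory chain from both genomes is not borne out, since the nuclear-encoded list had a median of 0.03, at percentile 73.9. Less nuclear RNA in the deeper library stays open. The nuclear noncoding RNAs lay at percentile 3.16 of GC-matched lists. Rn7sk, a nuclear RNA, was higher in the deeper library at 0.55. It shares 82.1% of its 31-mers with other genes, so its ratio cannot decide the question. Whether GC content accounts for the lower median of the nuclear noncoding RNAs is not settled. Their median was -0.34 with the GC trend taken out against -0.29 before, but the -0.34 was not placed among random lists. The -0.29 lay inside the range of GC-matched lists (-0.32 to 0.42). The labels name no difference between the 2 inputs that could be tested as a further explanation.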
